A study of Rattus norvegicus with 10 samples.

How the data were processed

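RNA was sequenced from the gastric mucosa of Sprague Dawley rats after oral dosing with a non-steroidal anti-inflammatory drug (NSAID), from controls whose labels name no treatment, and after indomethacin preceded by honokiol. The labels give epithelial cells as the cell type. The labels gave 5 groups of 2 libraries. The time label of the honokiol libraries has the length of the lead of honokiol before indomethacin and was read as that lead, with sampling at 4 h as in the general protocol. Per the labels' protocols, total RNA was depleted of ribosomal RNA, made into stranded libraries and sequenced as paired ends. The deposited values are whole-number counts per gene with a different total in each library, so they were taken as raw counts, and their columns have the layout of featureCounts per the file headers. Per the submitters' processing notes, bcl2fastq, FastQC 0.11.7, cutadapt 1.16, HISAT2 2.1.0, SAMtools, featureCounts and DESeq2 were used. The genome build, the strand setting of the counter and its treatment of reads with several matches are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart, and copies of a gene family may share reads.

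Each file listed the same 32623 Ensembl gene identifiers with exon coordinates and lengths. Exon numbers given here count the distinct exon coordinates listed for a gene, which may come from more than 1 transcript. The aspirin and diclofenac files ended in 2 empty lines each and the other 6 files in 1, and these lines held no count and were skipped. The files do not pair identifiers with gene names, and 0 of the 32623 identifiers matched the reference table of gene symbols. For that reason no gene is named, at most 2 identifiers that rose and 2 that fell are printed, and other features are described by position. The 51 gene lists fixed before the data were examined could not be applied, and the naming rule could not be used as written, since it asks for a symbol. That rule takes genes called in the same direction with all 3 drugs, at an average log2 CPM of at least 1 and with every drug library on 1 side of both controls, in order of the mean log2 fold change. Without its symbol condition it gave the 4 printed identifiers. Features described by position were chosen after their values were seen.

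Library totals ran from 23892226 to 44977459 counts. The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the default filterByExpr settings (minimum count 10, minimum total 15), robust moderation, and group as the only term. All 10 libraries entered 1 fit, which left 5 residual degrees of freedom, and 16346 genes were tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. Values per library are TMM-scaled CPM, the counts scaled to a common library total, computed here from the deposited counts. Where all libraries of a group held 0 counts, a fold was computed against a floor of 3 counts over the group, and medians from the group-only model were taken again with such genes at that bound. For honokiol plus indomethacin against control, 10 of the 681 genes and 1 of the 106 described in the report were left out of these medians, because both groups were at or under the floor. The median of the 681 genes was then 1.05 with indomethacin, that of the 106 genes was 0.58 for honokiol plus indomethacin against control, and the others were the same. Ratios of few counts carry exact 95% Poisson intervals, and shares of a single library carry exact Clopper-Pearson 95% intervals. Both cover counting error only. Groups of features were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, all in limma 3.58.1. Nothing in the labels says whether the 2 libraries of a group came from separate animals. Control libraries held 3582 and 1 counts on Y-chromosome features and indomethacin libraries 4438 and 2, which 1 animal would not give. For the other groups this stays open, so p-values measure the spread between these libraries.

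Counts on 7 features of the Y chromosome, those with at least 50 counts in all and 0 in at least 1 library, were summed per library. A library was taken to hold Y reads at over 1000 such counts. After this was seen, a term for Y reads was added to the model as an alternative, and fits on libraries of a single Y-read state were made. Where a fit left a group with 1 library, that library was assumed to vary like the groups that kept both: aspirin and diclofenac among libraries without Y reads, and honokiol plus indomethacin alone among those with them. Other alternatives chosen after seeing the data removed each library's trend with gene length or left 3 loci out. Alternatives fixed before the data were examined were RLE factors, no low-count filter, a stricter filter (at least 1 CPM and 10 counts in 2 libraries), DESeq2 1.42.0, fits on the 4 libraries of a comparison, a replicate block, an added 2-fold threshold, leaving out the 50 most abundant genes, and leaving out each library. Shared controls were addressed by 20 simulations of unchanged groups against the same controls, with each gene drawn on its own. These cannot show how shared controls raise the overlap of called genes, and they leave out variation shared between genes.

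The steps were tested on simulated data with 200 changed genes per comparison, 100 at each fold. For indomethacin against control, 20% of the 2-fold changes and 82% of the 4-fold changes were recovered, with 5 false calls among 16041 genes. The shares were 11% and 77% for diclofenac, with 11 false calls among 15943 genes, and 16% and 84% for aspirin, with 9 among 16038 genes. For honokiol plus indomethacin against indomethacin they were 17% and 70%, with 9 false calls among 16073 genes. With 200 changed genes the adjusted threshold is stricter than where many genes are called. The shares thus do not measure recovery with diclofenac or aspirin, where 1286 and 2903 genes were called.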

Results

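Transcripts of rat gastric mucosa were counted in 10 libraries, 2 in each of 5 groups. NSAIDs, which inhibit cyclooxygenases, were given by mouth and tissue was taken 4 h later. The drugs were indomethacin at 48 mg/kg, diclofenac at 75 mg/kg and aspirin at 400 mg/kg. A further group received honokiol, a lignan of magnolia bark, at 40 mg/kg into the peritoneum 30 min before indomethacin. The time label of this group is not 4 h but has the length of that lead, and was read as the lead, so sampling at 4 h rests for this group on the general protocol. Groups with honokiol alone or vehicle were not analysed here, nor was ibuprofen. Totals ranged from 23892226 to 44977459 counts and 19478 to 20722 genes had counts. Replicates correlated at r = 0.963 to 0.976 across genes in log2 CPM, and their counts differed by far more than sampling noise, with chi-square per degree of freedom from 38.1 to 389. The genome build of the coordinates is not given in the sources used here.

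Among the most abundant single features were mitochondrial ones and 1 nuclear gene. Short single-exon features outside the mitochondrion, 6120 of at most 350 nt, together took 20.7% to 23.4% of counts as group means. A pair of mitochondrial features at positions where the ribosomal RNA genes lie took 32.4% ± 0.099 of counts in control, 24.5% ± 7.3 with indomethacin, 29.9% ± 2 with honokiol plus indomethacin, 20.7% ± 0.68 with aspirin and 18.9% ± 0.34 with diclofenac (SD, n = 2 each). The indomethacin libraries lay apart, at 29.66% in replicate 1 (95% interval 29.65 to 29.67) and 19.29% in replicate 2 (19.27 to 19.3). Neither feature at the ribosomal positions passed the test against control with diclofenac (edgeR adjusted p = 0.43 and 0.2) or aspirin (0.58 and 0.083). With aspirin their log2 fold changes had opposite signs, at 0.38 ± 0.46 and -1.18 ± 0.45 (SE). A 9-exon gene on chromosome 9 from 15266699 to 15274917 took 14.3% ± 4.3 of counts in control and 21.3% ± 5.3 with diclofenac (SD, n = 2 each), a log2 fold change of 0.45 ± 0.39 that did not pass the test (SE, edgeR adjusted p = 0.49). The 50 most abundant features held 73.1% to 76.6% of counts as group means. A set of 3 loci, on chromosome 1 from 11963836 to 11968939 and on chromosome 14 from 46523594 to 46529375 and from 46653040 to 46657975, took 0.16% ± 0.013 of counts in control, 1.22% ± 0.29 with indomethacin, 0.195% ± 0.075 with honokiol plus indomethacin and 9.63% ± 1.5 with aspirin (SD, n = 2 each), and 12.07% of diclofenac replicate 1 (95% interval 12.06 to 12.08) against 0.6519% of replicate 2 (0.6495 to 0.6544). Of the 3, only the locus at 46523594 passed the test against control, with aspirin (log2 fold change 4.93 ± 1.02) and diclofenac (4.49 ± 1; SE, edgeR adjusted p = 0.019 and 0.033). The others had an edgeR adjusted p of 0.054 and 0.068 with aspirin and 0.09 and 0.11 with diclofenac, and none of the 3 passed with indomethacin (0.57, 0.41 and 0.6). None of the 3 passed with a term for Y reads. The locus at 46523594 then had log2 fold changes of 4.8 ± 1.25 with aspirin and 4.36 ± 1.23 with diclofenac (SE, edgeR adjusted p = 0.085 and 0.14).

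Libraries within groups differed in reads on the Y chromosome. Control replicate 1, indomethacin replicate 1 and both honokiol plus indomethacin libraries held 2733 to 4438 counts on 7 Y-chromosome features. The other 6 libraries, among them both aspirin and both diclofenac libraries, held at most 47, a value reached in diclofenac replicate 1. In the 6 libraries with few or no Y counts, 3 features of the X chromosome were higher. One of these, from 74304292 to 74345507, had at least 20.6 CPM in each of those 6 and at most 3.93 CPM in the other 4. The other 2 features lie within its span, so the 3 represent 1 region. Y reads were thus uneven between control and the aspirin and diclofenac groups, and between indomethacin and the honokiol group, so the counts of called genes below are given also with a term for Y reads, an alternative chosen after seeing the data. The labels do not give the sex of the animals, and whether a library carries a wrong label was not tested. The deposited tables of the aspirin and diclofenac libraries ended in 2 empty lines each and those of the other 6 libraries in 1.

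**Figure D1:**
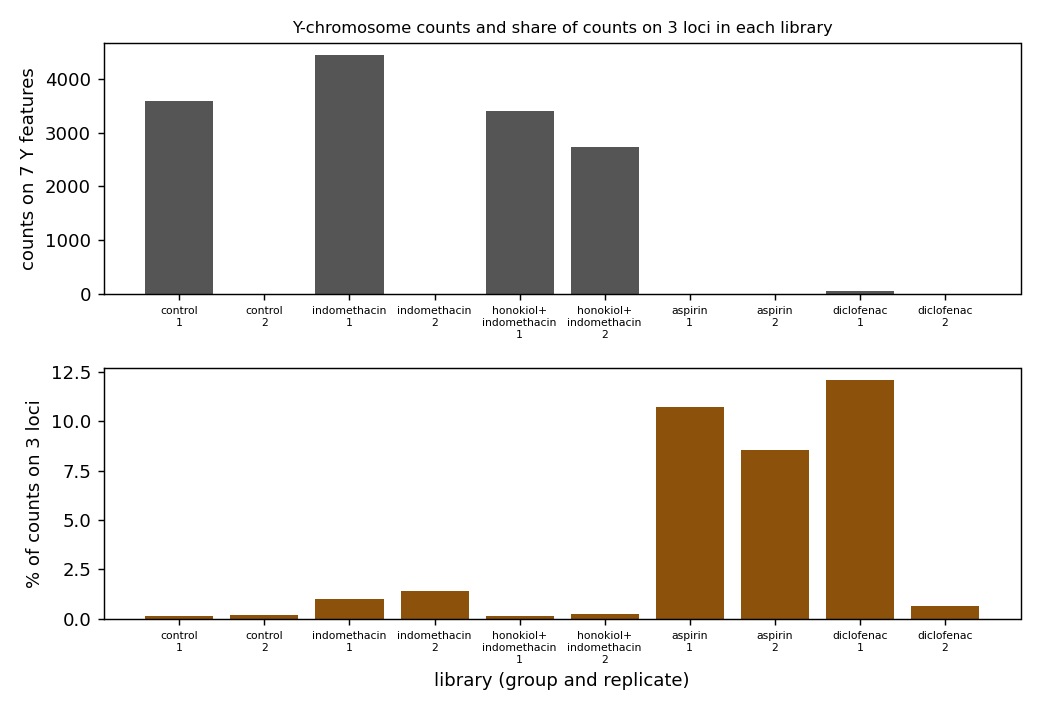
Counts on 7 Y-chromosome features (upper bars) and the percentage of all counts on 3 loci of chromosomes 1 and 14 (lower bars) in each of the 10 libraries, named by group and replicate. Y counts are 2733 to 4438 in 4 libraries and at most 47 in the other 6, and the 3 loci reach 12.07% in diclofenac replicate 1 against 0.652% in diclofenac replicate 2.

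Indomethacin against control addressed the response of the mucosa to this drug. Nearly all called genes were higher: 123 rose and 4 fell, with a median absolute log2 fold change of 2.56 over the called genes. Of these genes, 46 went from under 1 CPM in both controls to at least 1 CPM in both indomethacin libraries. The gene ENSRNOG00000002843 on chromosome 14 (18860264 to 18862407, 4 exons) had 0 counts in both controls and 2.63 CPM ± 0.566 with indomethacin (SD, n = 2). Against a floor of 3 counts over the control group it was 54.4-fold higher, and the lower 95% Poisson limit of the ratio was 43.8. ENSRNOG00000028616 on chromosome 3 (171213936 to 171219871) had 2 counts in the controls and 152 with indomethacin, a ratio of 62.6 (95% Poisson interval 17 to 522), and its fitted log2 fold change was 5.84 ± 0.81 (SE, edgeR adjusted p = 0.0093). ENSRNOG00000029792 and ENSRNOG00000047786, both on chromosome 17, fell by 1.15 ± 0.23 and 1.11 ± 0.22 on the log2 scale (SE, edgeR adjusted p = 0.041 for both). A term for Y reads gave 116 calls, all higher, of which 101 were among the 127, and the edgeR adjusted p of both falling genes became 0.051, at the same log2 fold changes of -1.15 and -1.11. With either control library left out neither of the rising identifiers was called, though their fitted log2 fold changes were 9.54 and 9.55 (9.53 with all libraries) for ENSRNOG00000002843 and 5.81 and 5.88 for ENSRNOG00000028616. The falling ones were not called without any 1 of the control, indomethacin or honokiol plus indomethacin libraries, at log2 fold changes from -1.27 to -0.99 and from -1.2 to -0.99. The count was 1 without control replicate 2, 21 without control replicate 1, 52 without indomethacin replicate 2, and 200 and 192 without diclofenac replicate 1 and 2. Within the libraries without Y reads 39 genes were called and within those with Y reads 135, but each count sets 1 library against 1, with the spread taken only from other groups, so neither bears on the 127.

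Diclofenac against control gave 778 higher and 508 lower genes, with a median absolute log2 fold change of 1.33. Of the called genes, 137 went from under 1 CPM in both controls to at least 1 CPM in both diclofenac libraries and 36 the other way. ENSRNOG00000002843 reached 8.37 CPM ± 0.795 (SD, n = 2), 172-fold over the control floor, with a lower 95% Poisson limit of 139. ENSRNOG00000028616 had 568 counts, 203 times the control level (95% Poisson interval 56 to 1680), and rose by a fitted log2 fold change of 7.53 ± 0.76, while ENSRNOG00000029792 fell by 1.45 ± 0.23 and ENSRNOG00000047786 fell by 1.44 ± 0.22 (SE, edgeR adjusted p = 0.0013, 0.0054 and 0.0047). Adding the Y-read term left 280 genes higher and 103 lower, and 369 of these 383 had been called without it. Within the libraries without Y reads, 2 against 1 with the lone control taken to vary like the other groups, the count was 150, and ENSRNOG00000002843 and ENSRNOG00000047786 were not called, at fitted log2 fold changes of 11.29 and -1.51 against 11.19 and -1.44 with all libraries. Single libraries moved it to 241 higher and 78 lower genes without control replicate 1, 485 and 81 without diclofenac replicate 1, and 351 and 73 without diclofenac replicate 2. Without control replicate 2 it was 637 and 636, so the balance of higher and lower genes depended on single libraries.

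Aspirin against control gave 1553 higher and 1350 lower genes, with a median absolute log2 fold change of 1.14. From under 1 CPM in both controls to at least 1 CPM in both aspirin libraries went 259 called genes, and 34 went the other way. ENSRNOG00000002843 had 4.39 CPM ± 3.4 (SD, n = 2), 101-fold over the control floor, with a lower 95% Poisson limit of 81.6. ENSRNOG00000028616 had 536 counts, 238 times the control level (95% Poisson interval 65.5 to 1970), with a fitted log2 fold change of 7.66 ± 0.76 (SE, edgeR adjusted p = 0.0012). ENSRNOG00000029792 fell by 1.6 ± 0.23 and ENSRNOG00000047786 fell by 1.49 ± 0.22 (SE, edgeR adjusted p = 0.0039 and 0.0044). The Y-read term gave 484 higher and 199 lower genes, 662 of them called without it as well. The count was 184 within the libraries without Y reads, again with a lone control, where ENSRNOG00000002843 was not called at a fitted log2 fold change of 10.39 against 10.28 with all libraries, 467 without control replicate 1 (334 higher, 133 lower) and 462 without aspirin replicate 1 (393 higher, 69 lower). Without aspirin replicate 2 it was 1769 higher and 1837 lower, so here too the balance depended on single libraries. An added 2-fold threshold left 1811.

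**Figure D2:**
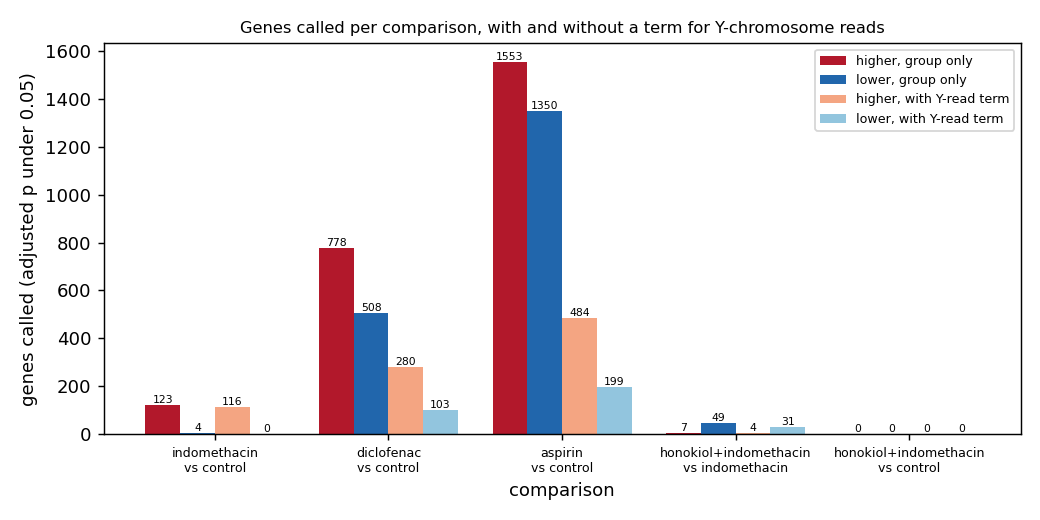
Number of genes called at an edgeR adjusted p under 0.05 (vertical axis) in 5 comparisons, higher (red) and lower (blue), from the fit with group only (dark) and with a term for Y-chromosome reads (pale). Aspirin falls from 1553 higher and 1350 lower genes to 484 and 199, and indomethacin moves from 123 and 4 to 116 and 0.

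All 3 drugs raised 106 genes and lowered 2, counts that cannot exceed the 123 higher and 4 lower genes called with indomethacin. Independent lists would share 0.56 and 0.01. In 20 simulations of unchanged groups against the same controls none was shared by all 3. With no gene changed few calls are made, so that result cannot show how shared controls raise the overlap. Median log2 fold changes over the 106 were 2.43 with indomethacin, 2.75 with diclofenac and 2.62 with aspirin. Of the 127 genes called with indomethacin, 114 were also called with diclofenac or aspirin. Diclofenac and aspirin raised 681 genes together and lowered 400, where independent lists would share 73.9 and 42. Of these 400, 394 lay below 0 with indomethacin, at a median of -0.4, in a comparison that shares the controls the set was chosen against. Across genes, which are not independent replicates, log2 fold changes correlated at r = 0.74 for indomethacin and diclofenac, 0.7 for indomethacin and aspirin and 0.87 for diclofenac and aspirin. The simulated values were 0.52, 0.51 and 0.51. Covariances were 0.53, 0.54 and 0.86 against a simulated 0.1 for each pair. The controls are too few to be split, so part of the excess in overlap may come from sharing them. With the Y-read term all 3 drugs raised 87 genes, 78 of them among the 106, and neither of the 2 lowered genes was called with indomethacin. The count of 108 fell to 1 without control replicate 2, 20 without control replicate 1 and 32 without indomethacin replicate 2.

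The drugs themselves were compared at the doses given, which differ. Indomethacin and diclofenac are arylacetic acids and aspirin is acetylsalicylic acid. Between indomethacin and diclofenac 3 genes were called, and the same 3 differed between indomethacin and aspirin, in comparisons that share the indomethacin libraries. A single-exon feature of 274 nt on chromosome 3 (75024206 to 75024479) had 11.9 CPM ± 2.56 with indomethacin, 1.72 ± 0.00699 with diclofenac, 2.1 ± 0.419 with aspirin and 14.5 ± 2.18 in control (SD, n = 2 each). A 9-exon gene on chromosome 2 (243502073 to 243516532) had 55 CPM ± 7.07 with indomethacin, 9.09 ± 1.91 with diclofenac, 10.7 ± 2.64 with aspirin and 51 ± 16.8 in control. A 24-exon gene on chromosome 7 (14529482 to 14574361) had 5.2 CPM ± 1.29 with indomethacin, 0.198 ± 0.0561 with diclofenac, 0.189 ± 0.201 with aspirin and 0.306 ± 0.103 in control. With honokiol plus indomethacin the 3, in this order, had 10.6 CPM ± 1.52, 45.4 ± 5.19 and 2.01 ± 0.777. On chromosomes 3 and 2 only aspirin and diclofenac were thus low. Their files alone ended in 2 empty lines, so a batch that follows these drugs cannot be told apart from them there. The log2 differences of the 3 genes between indomethacin and diclofenac were 2.78 ± 0.25, 2.6 ± 0.28 and 4.69 ± 0.59 (SE, edgeR adjusted p = 0.0026, 0.01 and 0.029). Against aspirin they were 2.51 ± 0.25, 2.36 ± 0.28 and 4.92 ± 0.62 (SE, edgeR adjusted p = 0.0076, 0.025 and 0.03). When Y reads entered the model, those on chromosomes 2 and 3 were still called against diclofenac and that on chromosome 3 against aspirin. The log2 differences of the others were then 4.39 ± 0.62 on chromosome 7 against diclofenac, and 4.62 ± 0.65 on chromosome 7 and 2.12 ± 0.26 on chromosome 2 against aspirin (SE, edgeR adjusted p = 0.093, 0.13 and 0.054). Diclofenac and aspirin differed in 0 genes by edgeR, with 852 at an unadjusted p under 0.05, and in 7 by DESeq2. Adding Y reads to the edgeR model again gave 0, with 858 at an unadjusted p under 0.05. With no change a share of 0.05 of the 16346 tested genes would fall there on average, and 852 and 858 lie near it. For ENSRNOG00000028616 the log2 difference between diclofenac and aspirin was -0.13 ± 0.42 (SE). A low count does not show that drugs acted alike: DESeq2 called 165 genes between indomethacin and diclofenac and 469 between indomethacin and aspirin. The edgeR count against diclofenac was 0 without diclofenac replicate 1, with 988 genes at an unadjusted p under 0.05, 63 without replicate 2, 7 without indomethacin replicate 2 and 5 without either honokiol plus indomethacin library. Of the 3 genes, 2 were called against diclofenac without either control library and 2 against aspirin without aspirin replicate 1. Without indomethacin replicate 1, 2 genes were called against each drug, of which 1 was among the 3. Within the libraries without Y reads, with a lone indomethacin library, 4 genes were called against diclofenac and 3 against aspirin, and 2 of the 4 but 0 of the other 3 were among those called by edgeR with all libraries (1245 genes at an unadjusted p under 0.05 against aspirin). Against aspirin it was 570 without aspirin replicate 2, 19 without indomethacin replicate 2, 56 and 55 without diclofenac replicate 1 and 2, and 5 without any 1 of the control or honokiol plus indomethacin libraries. Diclofenac and aspirin differed in 15 and 27 genes without diclofenac replicate 1 and 2 and in 4 without aspirin replicate 2.

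Honokiol before indomethacin was compared with indomethacin to ask whether it alters the response, since the protocol speaks of protection by honokiol. Most called genes were lower: 49 fell and 7 rose. Of the 49, 44 had been called higher with indomethacin, which shares the indomethacin libraries, and 38 were among the 106 raised by all 3 drugs. ENSRNOG00000002843 had 2 counts in the honokiol group and 198 with indomethacin, a ratio of 0.0131 (95% Poisson interval 0.00158 to 0.048, edgeR adjusted p = 0.022). ENSRNOG00000028616 had a log2 difference of -0.91 ± 0.48, and ENSRNOG00000029792 and ENSRNOG00000047786 had 0.15 ± 0.23 and 0.16 ± 0.22 (SE), none past the threshold. Among called genes with an average log2 CPM of at least 1, the largest rise was in a 9-exon gene on chromosome 15 (49069145 to 49177166), with 5.49 CPM ± 0.25 against 1.1 ± 0.22 (SD, n = 2) and a log2 difference of 2.31 ± 0.39 (SE, edgeR adjusted p = 0.036). A model with Y reads gave 31 lower and 4 higher genes, 25 of them called without it, and neither ENSRNOG00000002843 nor the chromosome 15 gene was called (edgeR adjusted p = 0.1 and 0.13). Their fitted log2 differences were then -5.87 ± 0.98 and 2.3 ± 0.47, against -6.11 ± 0.84 and 2.31 ± 0.39 without the term (SE). ENSRNOG00000002843 was also not called without indomethacin replicate 2 or either honokiol plus indomethacin library, at fitted log2 differences from -6.2 to -5.87. The count was 0 without honokiol plus indomethacin replicate 1, with 1272 genes at an unadjusted p under 0.05, 3 without replicate 2, 9 without indomethacin replicate 2, and 118 and 116 without diclofenac replicate 1 and 2. Within the libraries with Y reads, 2 against 1 with the spread taken only from the honokiol plus indomethacin pair, it was 191.

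In the group-only model, a check that shares no library used the genes called with both diclofenac and aspirin. Of the 681 higher genes, 618 lay below 0 in honokiol plus indomethacin against indomethacin, 40 were called lower where independent lists would share 2, and the median log2 difference was -0.68 (quartiles -1.34 and -0.27). The 400 lower genes had a median of 0.11, at p = 0.35 by camera with an estimated correlation. With the Y-read term 20 of the 681 genes were called lower, and the medians of the 2 sets were -0.57 and 0.01. Among libraries matched for Y reads, with a lone control for choosing the set and a lone indomethacin library for testing it, the 116 genes called higher with both drugs without Y reads had a median of -0.94 (quartiles -1.67 and -0.48). The set of 681 passed camera at the preset correlation (p = 3.3e-43), with an estimated correlation (p = 0.0053) and fry (p = 0.0011). The matched set gave p = 0.13 with an estimated correlation. Across 16346 genes the honokiol difference correlated with the mean of diclofenac and aspirin against control at Pearson's r = -0.4 and Spearman's rho = -0.21, where 20 simulations gave an r of -0.032 to 0.013. Genes are not independent replicates. The simulations drew each gene on its own, so their range leaves out variation shared between genes and cannot judge the observed r. The model with Y reads gave -0.383 and -0.188. Its term is estimated from the control and indomethacin pairs alone and enters the 2 sides with opposite signs. Error in the term can thus by itself make r negative, so these values are no independent check. Matched libraries, which share none, gave -0.336 and -0.12 over 15702 genes. Without indomethacin replicate 2 the r was -0.224.

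**Figure D3:**
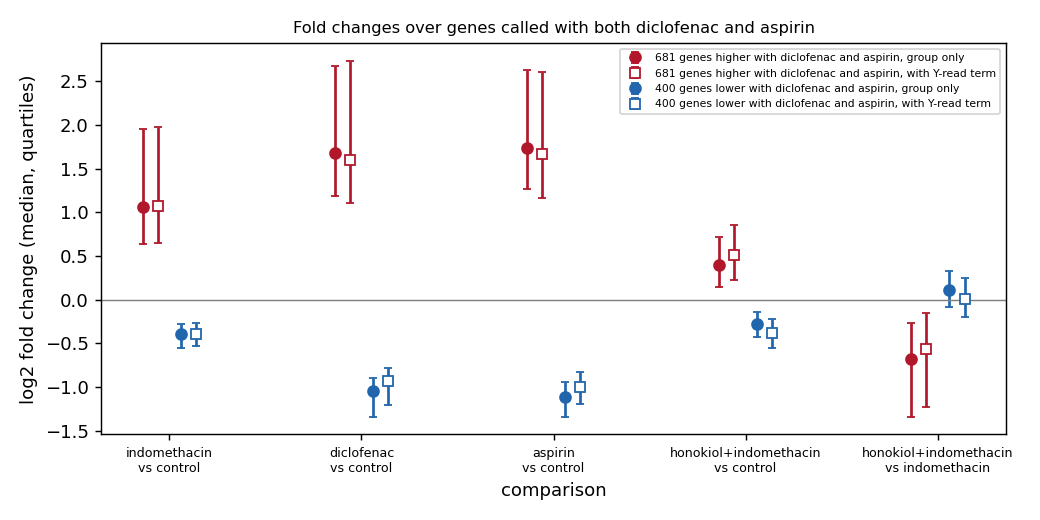
Median log2 fold change with quartiles (vertical axis) over the 681 genes higher (red) and the 400 genes lower (blue) with both diclofenac and aspirin, in 5 comparisons, from the fit with group only (filled) and with the Y-read term (open). The 681 genes have a median of 1.06 with indomethacin and 0.39 with honokiol plus indomethacin against control, both relative to the controls the set was chosen against.

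Honokiol plus indomethacin against control gave 0 genes by edgeR, with 816 at an unadjusted p under 0.05 and a lowest adjusted p of 0.2. The 816 lie near the share of 0.05 of the 16346 tested genes that no change would give on average. DESeq2 called 17. The Y-read term again gave 0 genes by edgeR, with 1508 at an unadjusted p under 0.05. The 681 genes had a median log2 fold change of 0.39 against control (quartiles 0.14 and 0.72), compared with 1.06 with indomethacin (0.64 and 1.95). The 106 genes raised by all 3 drugs had a median of 0.59 (quartiles 0.26 and 0.98). Both sets were chosen for being higher than these same controls, a choice that by itself favours values above 0, so these medians are not independent of it. ENSRNOG00000028616 had 64 counts against 2 in control, a ratio of 34.2 (95% Poisson interval 9.09 to 289) and a fitted log2 fold change of 4.93 ± 0.87 (SE, edgeR adjusted p = 0.42). Without honokiol plus indomethacin replicate 2 the count was 1.

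Mitochondrial features of messenger length were followed as a group of 13, those over 200 nt beyond the ribosomal positions, chosen after seeing the data. All 13 lay below 0 with indomethacin and with diclofenac, at medians of -0.32 and -0.57, and 8 did with aspirin, at a median of -0.36. By edgeR 1 was called lower with diclofenac and 3 with aspirin, and the Y-read term left 0 called with either drug, with 3 at an unadjusted p under 0.05 with each. In honokiol plus indomethacin against indomethacin 12 lay above 0, at a median of 0.33. The adjusted camera p was 0.018 with indomethacin, 0.0046 with diclofenac, 0.15 with aspirin and 0.042 with honokiol, and with an estimated correlation it was 0.41, 0.7, 0.91 and 0.52, so no call of the group held. Medians with the Y-read term were -0.36 with indomethacin, -0.53 with diclofenac, -0.3 with aspirin and 0.3 with honokiol, at an unadjusted camera p of 0.011, 0.004, 0.086 and 0.18. Summed CPM of the 13 was 35900 ± 6200 in control, 27400 ± 8390 with indomethacin, 34200 ± 10200 with honokiol plus indomethacin, 23400 ± 622 with aspirin and 23500 ± 898 with diclofenac (SD, n = 2 each). Indomethacin and control lay less far apart than the libraries within either group, while the aspirin and diclofenac libraries, at 22820 to 24090, all lay below both controls, at 31510 and 40280.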

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

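The tests of Y reads, of gene length, of material from another tissue and of a blunted response were chosen after the results were seen. The contrast of drug against control differed between indomethacin and diclofenac in 3 genes by the test of the difference itself, and between indomethacin and aspirin in 3 genes, which were the same genes on chromosomes 2, 3 and 7. On chromosomes 2 and 3 indomethacin differed from control by log2 fold changes of 0.11 ± 0.27 and -0.29 ± 0.23, and diclofenac by -2.49 ± 0.28 and -3.08 ± 0.25 (SE). For these 2 genes a batch that follows aspirin and diclofenac cannot be told apart from the drugs.

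Many more genes were called with aspirin (2903) and diclofenac (1286) than with indomethacin (127), although few passed the test between drugs. Y reads were held by 4 libraries, and 3 X features of 1 region were higher in the other 6. Tissue of both sexes would give this, whether or not a library is wrongly labelled. Uneven Y reads are not the whole cause: the Y-read term gave 683 genes with aspirin against 116 with indomethacin. The 2241 aspirin calls not made with that term kept their direction, with a median absolute log2 fold change of 1.03 without the term and 0.89 with it and a median SE of 0.27 and 0.28, so lost calls alone do not show that Y reads caused a part of the pattern, which stays open. The term itself was called by edgeR for 10 of 16346 genes, 4 on Y, 3 on X and 3 elsewhere, with 954 at an unadjusted p under 0.05. It rests on the control and indomethacin pairs alone, so few calls do not exclude smaller differences. Removing the length trend left 3185 genes with aspirin and leaving out the 50 most abundant genes left 2821, so neither is the whole cause. The aspirin and diclofenac files each ended in 2 empty lines and all others in 1, so a processing batch that follows these drugs stays open and cannot be told apart from them, and neither a sex difference in the response nor a wrong label was tested.

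Genes higher with diclofenac and aspirin lay lower with honokiol before indomethacin than with indomethacin. The median over the 681 genes stayed below 0 with the Y-read term (-0.57, quartiles -1.23 and -0.15, p = 0.01 by camera with an estimated correlation), with the length trend removed (-0.72) and without either indomethacin library (-0.54 at its nearest to 0), so none of these is the whole cause. Libraries matched for Y reads gave -0.94 over 116 genes but decide little, as they set 2 honokiol plus indomethacin libraries against 1 with indomethacin (p = 0.13 with an estimated correlation). As a hypothesis, honokiol may blunt a response common to the NSAIDs, which should also raise the 400 genes lower with both drugs: their median was 0.11 (quartiles -0.08 and 0.33), which does not decide it. Honokiol alone, which could, was not analysed here, and a wrong label, another sampling time in the honokiol group (its time label was read as the lead) or an unrecorded batch that follows the groups stays open.

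At 3 loci, chromosome 1 from 11963836 to 11968939 and chromosome 14 from 46523594 to 46529375 and from 46653040 to 46657975, counts reached 10.7% (95% interval 10.69 to 10.71) and 8.557% (8.548 to 8.566) of the aspirin libraries and 12.07% (12.06 to 12.08) of diclofenac replicate 1. They were 0.16% ± 0.013 in control, 1.22% ± 0.29 with indomethacin and 0.195% ± 0.075 with honokiol plus indomethacin (SD, n = 2 each), and by edgeR only the first chromosome 14 locus passed, with aspirin and diclofenac (adjusted p = 0.019 and 0.033). With the Y-read term that locus did not pass, at log2 fold changes of 4.8 and 4.36 (edgeR adjusted p = 0.085 and 0.14). The share differed 18.5-fold between the diclofenac libraries, which held 47 and 0 Y counts, but this difference is part of the pattern itself. Control had 0.1515% (95% interval 0.1503 to 0.1528) in the library with Y reads and 0.1695% (0.1681 to 0.1709) in the other. Indomethacin had 1.021% (1.018 to 1.024) with Y reads and 1.425% (1.421 to 1.429) without. Uneven Y reads are thus not the whole cause. Another tissue in diclofenac replicate 1 might add to its share, as 20 genes were seen nearly in that library alone; other tissue in the aspirin libraries was not tested and stays open. Reads shared between copies stay open: the ratio of the chromosome 14 loci ranged 16.5-fold over all libraries but only 1.27-fold over the 3 with high shares, so the range set in advance, which the first value exceeds, was judged wrong after it was seen, for a locus that may have expression of its own.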

How the results depend on the processing

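Alternatives with the Y-read term, libraries of 1 Y-read state, the length trend or the 3 loci left out were chosen after seeing the data. Of 340 values under alternatives for the 4 printed identifiers, 307 kept their side of the threshold, 33 no longer passed it and 0 reversed. Against control a reversal was all but excluded, since they were chosen with every drug library on 1 side of both controls. Without a low-count filter counts rose to 834 with indomethacin, 2650 with diclofenac, 699 for honokiol against indomethacin, 153 for honokiol plus indomethacin against control, 872 and 1414 for indomethacin against diclofenac and aspirin, 140 for diclofenac against aspirin and 588 for all 3 drugs. That fit gave a median prior degrees of freedom without bound, against 6.59. DESeq2 gave 381 with indomethacin, 250 for honokiol against indomethacin, 17 for honokiol plus indomethacin against control, 165, 469 and 7 between drugs and 297 for all 3. Fits on 4 libraries gave 262, 527 and 1759 for indomethacin, diclofenac and aspirin, 250 and 3 for honokiol against indomethacin and control, and 60 and 57 between indomethacin and the others. The Y-read term gave 383 with diclofenac, 683 with aspirin, 35 for honokiol against indomethacin and 1 for indomethacin against aspirin. Libraries without Y reads gave 39 (1 library against 1), 150 and 184 for indomethacin, diclofenac and aspirin and 33 for all 3, and those with Y reads gave 191 and 5 for honokiol against indomethacin and control. Removing the length trend gave 5 for indomethacin against each other drug. A 2-fold threshold gave 1811 with aspirin. Leaving out 1 library gave 1 to 200 with indomethacin, 319 to 1434 with diclofenac, 462 to 3606 with aspirin, 0 to 118 for honokiol against indomethacin, 0 to 1 for honokiol plus indomethacin against control, 0 to 63, 2 to 570 and 0 to 27 between drugs, and 1 to 160 for all 3; a lone library is then assumed to vary like the others. The correlation of honokiol with the drugs was -0.16 without a filter, -0.477 with the stricter one, -0.336 in libraries matched for Y reads and -0.391 to -0.224 without 1 library. The cause was not tested for any of these. Replicate numbers were not taken to pair the libraries, as same-numbered deviations correlated at over 0.1 in 4 of 10 pairs of groups and below 0 in 6 (-0.26 to 0.3). The 3 pairs among control, indomethacin and honokiol plus indomethacin had 0.13, 0.3 and 0.14, and in control and indomethacin the number coincides with the Y-read state. With the replicate block the counts were 123, 935 and 2106 with indomethacin, diclofenac and aspirin, 71 and 0 for honokiol, 3, 3 and 0 between drugs, 104 for all 3 and a correlation of -0.412. The block ended the indomethacin calls of ENSRNOG00000029792 and ENSRNOG00000047786 at log2 fold changes of -1.14 and -1.11, so genes lowered by all 3 drugs went from 2 to 0 by edgeR, with 1482 genes at an unadjusted p under 0.05 with indomethacin. Gene list tests could not be run without symbols.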

Other observations

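All tests here were chosen after the values were seen, and no explanation is offered. Among genes lower with diclofenac, 43 lay on chromosome 17 where 15.3 would by chance (Fisher's exact test over genes, adjusted p = 2.1e-08 over 23 chromosomes). A window from 40 to 45 Mb held 21 of them among 67 tested genes. The 40 single-exon genes of that window, with a median length of 393 nt, had a median log2 fold change of -1.4 with diclofenac, -0.8 with aspirin and -0.2 with indomethacin. Single-exon genes elsewhere had a median of 0.03 with diclofenac. Summed CPM of the 40 was 447 ± 163 in control and 243 ± 47.6 with diclofenac (SD, n = 2 each), and control replicate 1 held 562 against 332.1 in replicate 2. The set gave p = 0.12 with an estimated correlation with diclofenac. With the Y-read term its median was -1.21, and chromosome 17 held 5 lower genes against 3.09 by chance (adjusted p = 1, Fisher's exact test). Chromosome 9 held 34 lower genes with diclofenac against 19.9 by chance (adjusted p = 0.026), and with the Y-read term 13 against 4.04 (adjusted p = 0.0044, Fisher's exact test). With aspirin 6 of 23 chromosomes passed among higher genes and 7 among lower genes, of which 3 and 3 held more genes than by chance and the rest fewer, and 1 and 0 passed with the Y-read term. The X chromosome, which passed with the term, held 22 higher genes against 51.7 by chance, and 4 against 16.1 with it (adjusted p = 3.7e-05 and 0.011, Fisher's exact test).

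Diclofenac replicate 1 held 20 genes with at least 20 counts and 10 times the CPM of any other library, where each of the other libraries held at most 2 such genes. The 20 took 21270 counts there, and the same genes were not absent elsewhere: the highest count of any of them in another library was 204. Of the 20, 4 lay on chromosome 10 and 3 on chromosome 7, among them features at 88118001 and 88055823 on chromosome 10 with 136 and 122 CPM, against at most 4 and 1.11 CPM elsewhere. The same library held 47 counts on Y features, where diclofenac replicate 2 held 0.

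Fold changes followed gene length in several comparisons. Across genes the Spearman correlation of log2 fold change with length was 0.022 with indomethacin, 0.17 with diclofenac, 0.2 with aspirin and 0.25 for honokiol plus indomethacin against control. Short single-exon features outside the mitochondrion, 658 of them tested, had a median of -0.36 for honokiol plus indomethacin against indomethacin, at an adjusted camera p of 7.2e-08 and of 0.15 with an estimated correlation.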
